A study of Mus musculus with 20 samples.

How the data were processed

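Epithelial cells were detached from intestinal tissue with EDTA and separated from immune cells by sedimentation, which left few CD45-positive cells, and RNA was extracted with TRIzol and labelled with a single dye, all per the labels' protocols. The series' design text gives 4 individual animals per genotype, so p-values measure the spread between animals. Each array's scanner output holds 45018 spots and was read with Feature Extraction 10.7.3.1. The intensity used here, the processed signal of each spot, is linear and had been background-subtracted, both per the file headers. Same-numbered wild type, Trif mutant, Tlr4 and Tlr3 knockout arrays shared 1 of 4 slides, each genotype at the same position on every slide, and each MyD88 array lay on a slide of its own.

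The authors' deposited value table proved to be the processed signal times 1 factor per array (1.58 to 2.27), which set its 75th percentile to 1499 to 1500, with values under 15 raised to 15. All values (100%) were equal to that product within 1 unit plus 0.1%. The table is linear and not centred, and its medians lay between 81 and 141.

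The 1639 control spots and the 67 to 210 spots per array with an outlier flag were left out; 0 spots were saturated. The spots of a probe were averaged as log2 values. Each array's 75th percentile was subtracted. Of 41174 probes, 31603 (76.8%) were well above background on at least 4 of 20 arrays and were kept, and of several probes of a gene the one with the highest mean signal stood for it. This left 21932 features, 15820 with a standard symbol. Gene names and mm9 positions are those of the files. Names were updated through RefSeq accessions (assembly GRCm38.p6, for names only), where 26690 probes matched and 3169 changed name. Where a gene was not well above background on any array of a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the lowest signal of a probe well above background or the probe's own, if higher.

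Group means over all 20 arrays were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (2.17 prior degrees of freedom), Benjamini-Hochberg adjustment and a threshold of 0.05, for 4 comparisons with wild type and 4 between mutants. The number of arrays limits the precision. The 33 gene lists, of cell types, gut regions and pathways, were tested with camera at an inter-gene correlation of 0.01 and again with an estimated one, under which no call held. Matching of list members to 1 feature each was corrected after values had been seen. Fisher's exact tests are two-sided.

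The tests, lists, alternatives and the rule for named genes were fixed before the data were examined, unless said otherwise. The rule took the targeted genes; the 10 largest rises and 10 largest falls among called genes with a standard symbol whose 4 mutant arrays all lay above or all below the 4 wild type arrays (5 each between mutants); and up to 4 members with the largest change of each called list and of the Paneth, antimicrobial, interferon and MHC class II lists. Printing 2 of those 4 was settled after values were seen. Some genes taken by the rule are not reported here.

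Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the deposited table, other filters on dim probes, a floor, all probes, a trended and robust moderation, array weights, only the genotypes compared, replicate or slide blocks, a log2 change of at least 1 and leaving out each array. Same-numbered wild type and Tlr4 knockout arrays deviated together (r = 0.35, 0.21, 0.18 and 0.17 over features), so the numbers pair these groups. On data simulated for each comparison over 21631 features, 6 to 15, 28 to 35, 43 to 47 and 49 to 50 of 50 genes changed by 0.5, 1, 2 and 3 (log2) were recovered, with 4 to 12 false calls among 133 to 154. For Trif mutants 5 of 5 shifted lists were, with 0 false, which does not bear on lists of correlated genes.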

Results

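Expression in intestinal epithelial cells of healthy 28-day-old mice was measured on 1 one-colour array per mouse. The labels give strain C57BBL6 but no gut region, which may differ by genotype. There were 4 animals per genotype: wild type, homozygous for the LPS allele of Trif, and lacking Tlr3, Tlr4 or MyD88. TLR3 and TLR4 are innate receptors for double-stranded RNA and lipopolysaccharide, and TRIF and MyD88 are adaptors of Toll-like receptors. The design asks how each gene shapes epithelial expression without infection. Of all probes 64.9% to 73.4% were well above background on the 16 arrays of scan day 1, and 71% to 85.5% on the 4 MyD88 arrays. These were scanned on another day and scanner, so for them genotype and scan cannot be told apart. Y-linked signal exceeded Xist, the RNA of the inactive X chromosome, on 0 of 4 wild type, 3 of 4 Trif mutant, 1 of 4 Tlr3, 0 of 4 Tlr4 and 4 of 4 MyD88 arrays, so sex was unequal between genotypes. Sex and genotype cannot be told apart between MyD88 knockouts and either wild type or Tlr4 knockouts. There a fit with Xist as a covariate takes its slope mostly from Trif mutants and Tlr3 knockouts, the only groups of mixed sex. Changes below are differences of mean log2 signal (± SE, n = 4 per genotype) with limma's adjusted p (the false discovery rate, FDR) over 21932 features, and camera's over 33 lists. "Rose" and "fell" stand for an adjusted p under 0.05, and "largest" for the order of the rule for named genes. "Estimated FDR" is camera's with an estimated correlation. Of a list, genes that went the other way are counted where there were any, and for genotypes on shared slides the range of its medians within the 4 slides follows the median of a called list. Counts of list members adjusted over the list alone were equal to those over all features unless given. Where another scaling moved such a count by over 1.5 times and at least 3 genes, the counts under quantile normalization, median scaling and normexp background correction follow in that order as "by scaling", for the first count unless said. Where leaving out 1 array changed a call given here, the adjusted p without it stands in parentheses.

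Tlr3 signal (chromosome 8, 46482009 to 46482068, mm9) was -8.53 ± 0.22 against -1.51 ± 0.15 (mean log2 ± SD) in Tlr3 knockouts and wild type. It was not well above background on any of the 4 knockout arrays and at least 27.9-fold lower (-7.02 ± 0.14, FDR = 1e-15). Tlr3 did not pass the test in the other genotypes (0.13 ± 0.14 in Trif mutants, -0.13 ± 0.14 in Tlr4 and -0.13 ± 0.14 in MyD88 knockouts), except in MyD88 knockouts under median scaling (-0.53, FDR = 0.0028). Myd88 (chromosome 9, 119245322 to 119245381) fell by 1.27 in MyD88 knockouts (0.86 ± 0.11 against 2.13 ± 0.13, FDR = 1.6e-06) while staying well above background on all 4 arrays. It did not pass in Trif mutants (-0.16 ± 0.11), Tlr3 (0.16 ± 0.11) or Tlr4 knockouts (-0.02 ± 0.11). Tlr4 (chromosome 4, 66503724 to 66503782) was well above background on 0 of 4 Tlr4 knockout arrays, 1 of 4 in wild type and 2 of 4 in each other genotype, with -8.41 ± 0.35 against -8.18 ± 0.44 in Tlr4 knockouts and wild type. Its change in Tlr3 knockouts passed with slide as a block (0.79, FDR = 0.034) and no other did, so it checks no label. Ticam1, which encodes TRIF (chromosome 17, 56409285 to 56409344), rose in Trif mutants (0.66 ± 0.13, FDR = 0.00062) and Tlr3 knockouts (0.61 ± 0.13, FDR = 0.0018). It fell in MyD88 knockouts (-0.45 ± 0.13, FDR = 0.0097) and was 0.17 ± 0.13 in Tlr4 knockouts. The labels do not say that the Trif allele removes the transcript, so Ticam1 signal does not check that label. After normexp Ticam1 did not pass in Trif mutants (0.53, FDR = 0.055) or MyD88 knockouts (-0.46, FDR = 0.14).

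**Figure D1:**
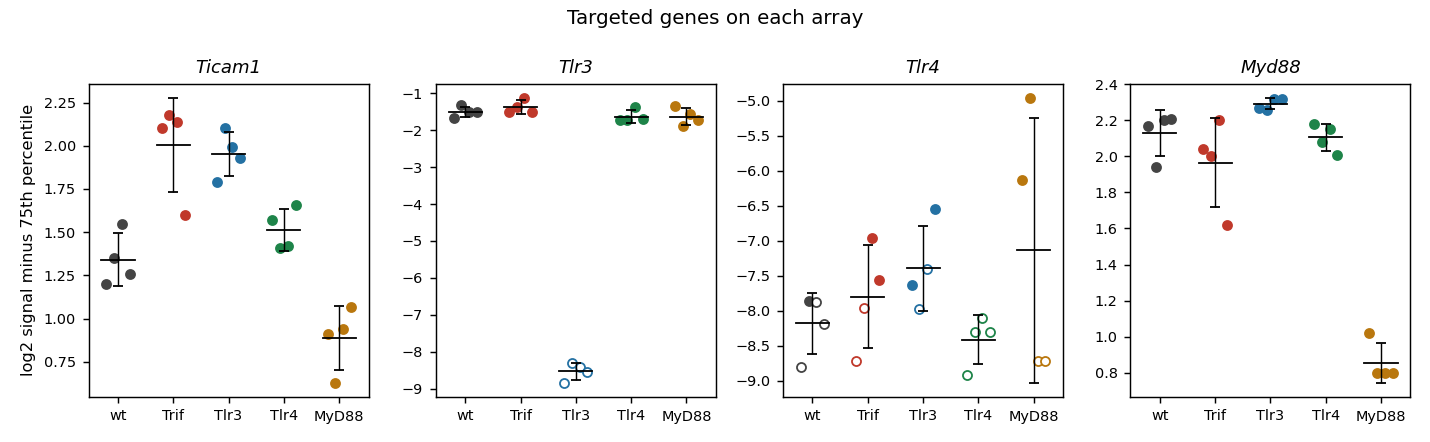
Log2 signal minus the array's 75th percentile (vertical axes) of Ticam1, Tlr3, Tlr4 and Myd88 on each of the 20 arrays by genotype (horizontal axes), filled where well above background, with the mean and SD of 4 arrays. Tlr3 averages -8.53 in Tlr3 knockouts and -1.51 in wild type.

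In Trif mutants the serum amyloid A genes, which encode acute-phase lipid-binding proteins and lie side by side on chromosome 7, were far below wild type. Saa2 (chromosome 7, 54009535 to 54009594) was -3.89 ± 0.79 against 5.10 ± 0.91 (mean log2 ± SD), a change of -8.99 ± 0.66 (FDR = 2.7e-07). Saa3 (53968031 to 53968090) was not well above background on any Trif mutant array and at least 285-fold lower (-8.93 ± 0.62, FDR = 2.1e-07), and Saa1 (53996070 to 53996129) changed by -5.95 ± 0.55. Retnlb (-7.88 ± 0.79), which encodes the goblet cell product RELM-beta, Pla2g5 (-7.62 ± 0.49), a secreted phospholipase A2, and the galactosyltransferase B3galt5 (-6.11 ± 0.54) followed. Cpn2 (-5.12 ± 0.48), Lrg1 (-4.53 ± 0.53) and Gpc3 (-4.48 ± 0.65) were also among the 10 largest falls (FDR up to 4.2e-05). The largest rises included the Y-linked Eif2s3y (8.48 ± 2.29), Ddx3y (6.94 ± 1.83) and Uty (4.24 ± 1.10). They were at least 77.1-, 26.4- and 4.58-fold higher on average, with 3 of 4 Trif mutant and 0 of 4 wild type arrays well above background. Among autosomal genes they were the vitamin E carrier Afm (3.88 ± 0.26), Lrmda (3.34 ± 0.25), Serp2 (3.30 ± 0.41), Srd5a2 (3.22 ± 0.61), the metallothionein Mt2 (3.22 ± 0.48), Cyp2c38 (3.19 ± 0.53) and the Wnt inhibitor Apcdd1 (3.17 ± 0.26) (FDR up to 0.00043). Srd5a2 and Cyp2c38 were at least 2.77- and 2.15-fold higher, on 3 of 4 arrays each. Other probes of Afm (0.51) and Apcdd1 (0.59) showed smaller values. With Xist as a covariate, a setting chosen after seeing the data, Eif2s3y, Ddx3y and Uty (FDR = 0.056 to 0.15) no longer passed. After normexp neither did Cyp2c38 and Gpc3 (FDR = 0.059 to 0.061).

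Dividing-cell genes fell in Trif mutants, with sex alike only on slide 4. Of cell cycle and DNA replication genes 37 of 38 fell (median -2.16, -2.91 to -1.06 on slide 4, FDR = 2.6e-23). Cdk1 (-3.32 ± 0.46) and Ccnb1 (-3.14 ± 0.45) changed most. Of crypt stem cell markers 17 of 22 fell and 1 rose (17, 17 and 11 by scaling, median -1.0, -1.51 to -0.53, FDR = 9.5e-07, both estimated FDR = 0.72). Olfm4 (-3.29 ± 0.58) and Myc (-2.46 ± 0.37) changed most. Of antimicrobial and mucosal defence genes 16 of 29 fell and 3 rose (16 and 4 adjusted over the list alone, median -1.28, -1.21 to -0.91, FDR = 9.2e-07), with Saa2 and Saa3 first. After normexp their median was -0.38, against 0.54 for all features. Of Paneth cell products other than defensins 8 of 21 fell and 3 rose (9, 8 and 4 by scaling, median -0.45, -0.46 to -0.33, FDR = 0.011, both estimated FDR = 0.085 to 0.72). Mmp7 (-2.86 ± 0.42), the protease that activates alpha-defensins, and Pla2g2a (-2.34 ± 0.47) (after normexp -0.98, FDR = 0.11) changed most. The alpha-defensin list was lower, though 0 of 11 fell and 0 rose (4, 0 and 0 by scaling, median -0.57, -0.92 to -0.35, FDR = 0.03). Its members furthest from 0, Defa-rs12 (-1.10 ± 0.54) and Defa22 (-0.96 ± 0.55), did not pass. Of MHC class II genes 6 of 8 fell and 1 rose (7 and 1 adjusted over the list alone, 6, 7 and 3 by scaling, median -1.39, -1.47 to -1.08, FDR = 0.011, both estimated FDR = 0.72). The invariant chain Cd74 (-2.73 ± 0.46) and H2-DMb1 (-2.54 ± 0.39) changed most. Of interferon-stimulated genes 13 of 43 fell and 4 rose (16, 17 and 7 fell and 1, 1 and 1 rose by scaling, median -0.41, -1.13 to -0.04, FDR = 0.00051). Ifi44 (-2.84 ± 0.49) and Zbp1 (-2.67 ± 0.33) changed most. On wild type replicate 4 this list lay at 1.08 (others -0.01 to 0.19), and without that array 8 fell (median -0.19), as without mutant replicate 2. Of endoplasmic reticulum stress and amino acid response genes 11 of 24 fell and 7 rose (12 and 7 adjusted over the list alone, 5, 4 and 2 rose by scaling, median -0.29, -0.32 to -0.15, FDR = 0.011, both estimated FDR = 0.72). The 2 largest changes, Psat1 (-2.69 ± 0.31) and Phgdh (-2.43 ± 0.39), are enzymes of serine synthesis. Of cholesterol synthesis genes 10 of 24 fell and 5 rose (2, 2 and 0 rose by scaling, median -0.39, -0.67 to 0.18, FDR = 0.048, estimated FDR = 0.72). The defensin list was not called with Xist (FDR = 0.25) or without mutant replicate 3 or 4 or wild type replicate 1 or 2 (0.053 to 0.086). The cholesterol list was not called without mutant replicate 1, 2 or 4 or wild type replicate 1 or 2 (0.079 to 0.15), and 5 or 6 of its genes fell without mutant or wild type replicate 1 or 2. With Xist 6 of these and 11 stem cell genes (median -0.60) fell. Members that rose against these lists, named after their values were seen, were H2-Oa (0.76) of MHC class II, the stem cell marker Igfbp4 (1.16) and the antimicrobial Zg16 (0.58), Reg3a (0.74) and Reg4 (1.30). Also rising were the Paneth list's Guca2b (0.83), Fgfrl1 (1.17) and Cd24a (0.58) and the interferon-stimulated Trim25 (0.46), Ifi35 (0.43), Cmpk2 (0.75) and Mx1 (0.74).

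Tuft cell markers rose in the same mutants: 20 of 22 rose and 1 fell (median 1.26, 0.73 to 1.72, FDR = 2.8e-05). The succinate receptor Sucnr1 (2.68 ± 0.46) and the cytokine Il25 (1.91 ± 0.57) changed most. Of absorptive enterocyte genes 26 of 36 rose (30 adjusted over the list alone, 7, 20 and 4 by scaling, median 0.63, 0.47 to 0.95, FDR = 7.8e-05, both estimated FDR = 0.72). The apolipoprotein Apoc3 (1.49 ± 0.25) and the fatty acid transporter Cd36 (1.36 ± 0.38) changed most. Of xenobiotic and retinoid metabolism genes 26 of 32 rose and 1 fell (28 and 1 adjusted over the list alone, 18, 23 and 16 by scaling, median 1.17, 0.89 to 1.38, FDR = 8.6e-05). The largest changes went opposite ways, Cyp1a1 (-3.47 ± 0.79) and Cyp2c55 (2.85 ± 0.63). Of PPAR-alpha targets and fatty acid oxidation genes 18 of 27 rose (10, 14 and 8 by scaling, median 0.62, 0.43 to 0.87, FDR = 0.0031, both estimated FDR = 0.72). Angptl4 (2.76 ± 0.43) and Pdk4 (2.31 ± 0.51) changed most. After normexp the absorptive (0.43) and PPAR-alpha (0.46) medians lay below the median of all features (0.54) and neither list was called (FDR = 0.25 and 0.23). With Xist Il25 and Cd36 (FDR = 0.065 to 0.078) did not pass, and 13 tuft, 15 absorptive, 15 xenobiotic and 11 PPAR-alpha genes rose. Goblet cell markers (median -0.08, FDR = 0.051) were called without mutant replicate 2 or 3 or wild type replicate 4 (0.007 to 0.023), and with Xist, normexp, quantile normalization, no filter or slide as a block (0.0013 to 0.037). No list of other cell types was called, with medians from 0.02 for B and plasma cells to 0.38 for mast cells.

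Between Trif mutants and wild type 9687 of 21932 features differed, 6237 higher and 3450 lower. The median feature lay at 0.19, and the higher share of 64.4% was 54.3% under quantile normalization and 53.6% under median scaling. With slide as a block 10436 features and the 13 lists above were called (FDR up to 0.028). Of called features, chosen on the same slides, 96.7% to 99.7% kept direction within each, which the choice favours. Position on the slide and genotype cannot be told apart. Called features numbered 5161 after normexp and 6311 with Xist.

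**Figure D2:**
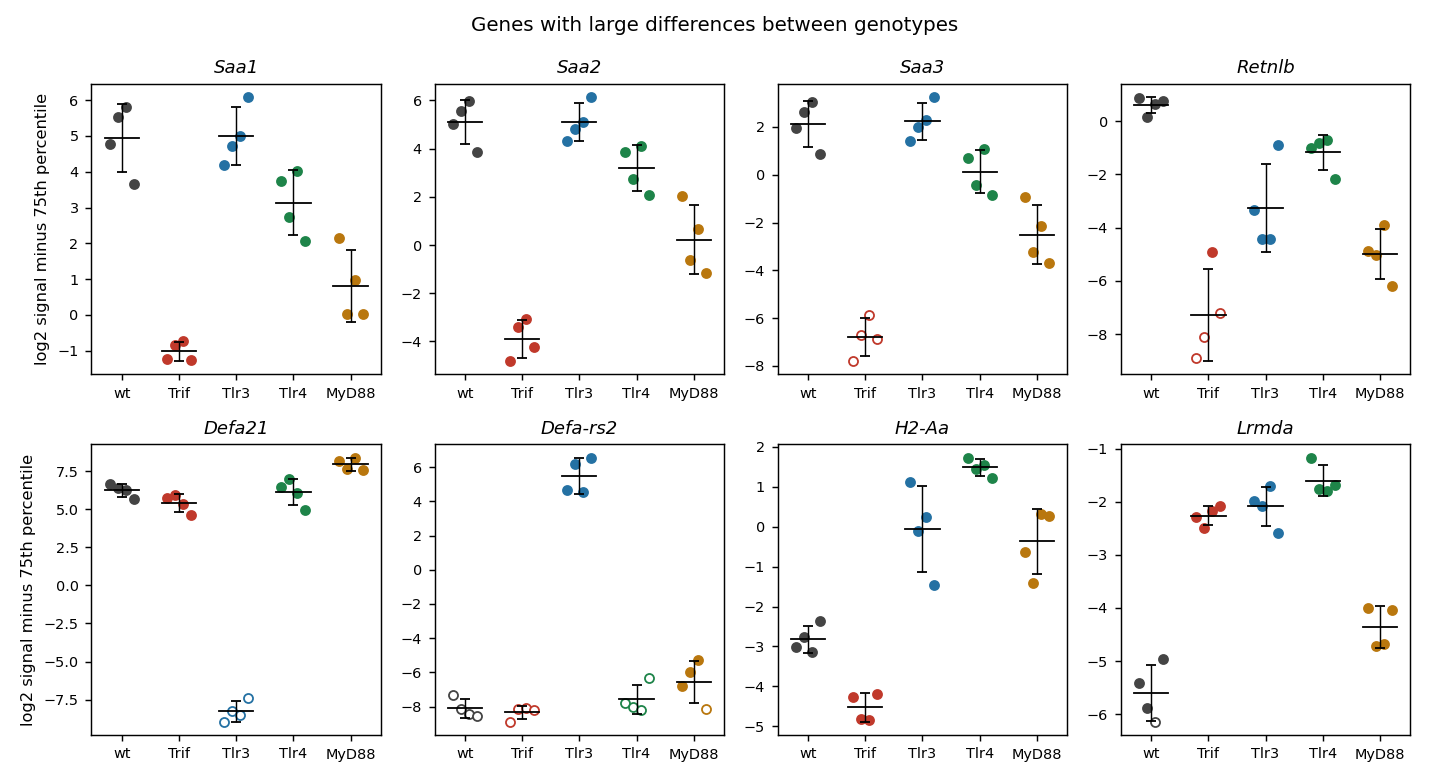
Log2 signal minus the array's 75th percentile (vertical axes) of 8 genes on each of the 20 arrays by genotype (horizontal axes), filled where well above background, with the mean and SD of 4 arrays. Defa21 averages -8.29 in Tlr3 knockouts and 6.26 in wild type.

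In Tlr3 knockouts the largest changes were in Paneth cell alpha-defensins, the antimicrobial peptides of the crypt base, which lie on the chromosome that carries Tlr3. Defa21 (chromosome 8, 22166004 to 22166063) was -8.29 ± 0.66 against 6.26 ± 0.42 (mean log2 ± SD), at least 6070-fold lower (-14.55 ± 0.40, FDR = 1.3e-13). Defa39 (22812996 to 22813001) fell by 5.26 ± 0.43 (FDR = 3.6e-07), and the related sequence Defa-rs2 was at least 3580-fold higher, 5.49 ± 1.04 against -8.11 ± 0.54 (13.60 ± 0.58, FDR = 8.5e-11). Of the alpha-defensin list 9 of 11 fell and 1 rose (9 and 2 adjusted over the list alone, median -1.89, -2.83 to -0.77, FDR = 1.6e-05, estimated FDR = 0.91). Tlr3 itself, Prm1 (-4.74 ± 0.66), Retnlb (-3.87 ± 0.79), Pcdh8 (-2.70 ± 0.45) and Tfec (-2.61 ± 0.33) also fell. Defa22 (-2.60 ± 0.55), the tight junction gene Cldn8 (-2.59 ± 0.58) and Bex4 (-2.58 ± 0.56) completed the 10 largest falls (FDR up to 0.0024). After Defa-rs2 the largest rises were Gpr61 (3.75 ± 0.76), Lrmda (3.51 ± 0.25), Htra4 (3.50 ± 0.36), the cytochrome P450 Cyp2a5 (3.30 ± 1.20), Afm (3.27 ± 0.26), and the keratin Krt12 (2.87 ± 0.26). The beta-carotene oxygenase Bco1 (2.83 ± 0.55), the MHC class II chain H2-Aa (2.77 ± 0.43), C4bp-ps1 (2.69 ± 0.21) and the clock gene Ciart (2.68 ± 0.55) followed (FDR up to 0.038). Gpr61 and Cyp2a5 were at least 3.12- and 2.97-fold higher, on 3 of 4 arrays each. Other probes of Prm1 (-0.05 to 0.87) and Tfec (0.07) did not share their falls, and that of Afm changed by 1.47. After normexp Gpr61, Pcdh8, Tfec, Cldn8 and Cyp2a5 (FDR = 0.091 to 0.5) no longer passed. Cyp2a5 also did not pass with slide as a block (0.053) or with any 1 array but knockout replicate 4 left out (0.053 to 0.14).

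**Figure D3:**
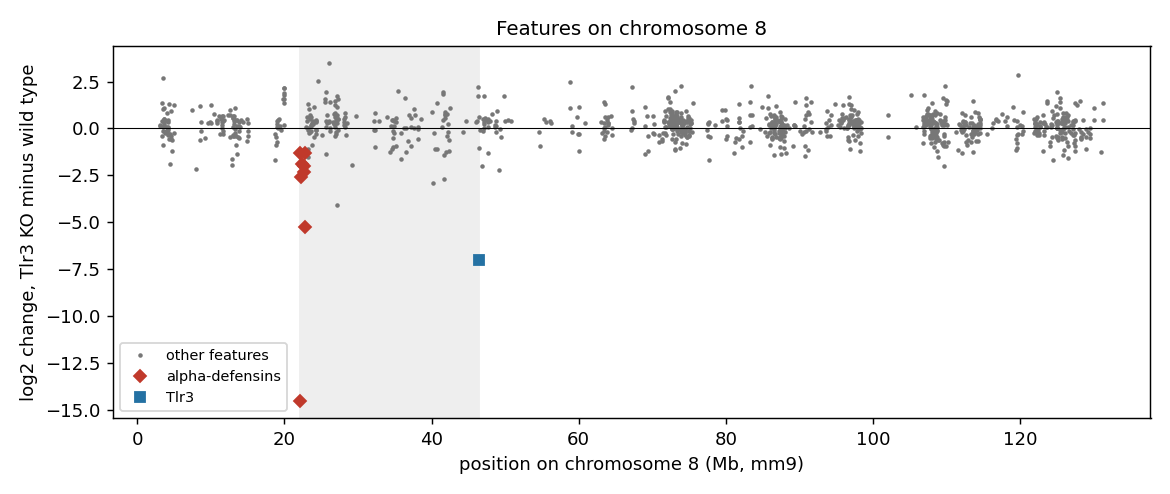
Log2 change in Tlr3 knockouts minus wild type (vertical axis) of features on chromosome 8 by position in Mb (horizontal axis, mm9). The 8 alpha-defensins with a position, from Defa21 (-14.55) to Defa6 (-1.32), and Tlr3 (-7.02) stand out, and the shaded part runs from 22166004 to 46482068.

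Other crypt genes fell in Tlr3 knockouts too. Of other Paneth cell products 9 of 21 fell and 3 rose (10 and 3 adjusted over the list alone, 11, 12 and 4 by scaling, median -0.63, -0.89 to -0.16, FDR = 0.0075). Mptx1 (-2.51 ± 0.64) and the lysozyme Lyz1 (-2.18 ± 0.52) changed most. Of cell cycle and DNA replication genes 37 of 38 fell (median -1.29, -1.69 to -0.82, FDR = 2.6e-16, both estimated FDR = 0.91). Mcm3 (-1.73 ± 0.42) and Kif11 (-1.73 ± 0.43) (other Kif11 probes -1.53 to 0.39) changed most. Of crypt stem cell markers 17 of 22 fell and 1 rose (17, 18 and 11 by scaling, median -0.99, -1.16 to -0.41, FDR = 3.1e-07). Olfm4 (-1.82 ± 0.58) and Tnfrsf19 (-1.77 ± 0.41) changed most. Without knockout replicate 3, 24 cell cycle and 11 stem cell genes fell. Of enteroendocrine markers 7 of 28 fell and 1 rose (12, 12 and 3 by scaling, median -0.27, -1.09 to 0.08, FDR = 0.0011, both estimated FDR = 0.91). The largest changes were the proglucagon gene Gcg (-1.62 ± 0.23) (a second probe 0.23) and, rising, the transcription factor Pax6 (1.20 ± 0.17). Olfm4 did not pass without knockout replicate 2 or 3 or wild type replicate 1 (0.062 to 0.067), nor Tnfrsf19 (-0.80, FDR = 0.23) after normexp. Antimicrobial genes were not called as a list (5 of 29 fell and 4 rose, 6, 6 and 2 fell and 0, 0 and 0 rose by scaling, median 0.06, FDR = 0.3), with Retnlb and Wfdc2 (-1.92 ± 0.37) changed most.

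Antigen presentation and enterocyte genes rose. Of MHC class II genes 7 of 8 rose (median 1.81, 0.62 to 2.81, FDR = 0.0091). H2-Aa and Cd74 (2.13 ± 0.43) changed most. Of interferon-gamma response genes 12 of 31 rose (14 adjusted over the list alone, 5, 4 and 2 by scaling, median 0.53, -0.18 to 0.86, FDR = 0.0089, both estimated FDR = 0.91). The tryptophan-degrading enzyme Ido1 (1.93 ± 0.52) changed most, and Iigp1 (1.67 ± 0.68), next, did not pass. Iigp1 passed without knockout replicate 4 or wild type replicate 1 or 4 (0.02 to 0.046). Interferon-stimulated genes were not called as a list (10 of 43 rose, 8, 5 and 6 by scaling, median 0.33, FDR = 0.13), with Mx1 (1.90 ± 0.27) and Stat2 (0.98 ± 0.21) changed most. They were called without knockout replicate 4 (0.039) or wild type replicate 4 (0.00016), after normexp (0.025), under quantile normalization (0.03) or without the filter (0.045). Of absorptive enterocyte genes 26 of 36 rose (28 adjusted over the list alone, 8, 14 and 8 by scaling, median 0.58, 0.44 to 0.82, FDR = 2.8e-05). The glucose transporter Slc5a1 (1.09 ± 0.23) and Slc3a1 (0.99 ± 0.24) (after normexp 0.97, FDR = 0.068) changed most. Of ileal genes 11 of 19 rose (12 adjusted over the list alone, 7, 10 and 4 by scaling, median 0.77, 0.37 to 0.97, FDR = 0.0099, both estimated FDR = 0.91). Bco1 and the bile acid-binding protein Fabp6 (1.55 ± 0.43) changed most. Of circadian clock genes 12 of 20 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.81, 0.62 to 1.05, FDR = 0.0099). Ciart and Hlf (2.61 ± 0.41) changed most. Of PPAR-alpha targets 14 of 27 rose and 1 fell (15 and 1 adjusted over the list alone, 7, 7 and 6 by scaling, median 0.51, 0.37 to 0.56, FDR = 0.019, both estimated FDR = 0.91). Angptl4 (2.47 ± 0.43) and Pdk4 (2.16 ± 0.51) changed most. Of xenobiotic metabolism genes 13 of 32 rose (15 adjusted over the list alone, 5, 3 and 2 by scaling, median 0.75, 0.00 to 1.07, FDR = 0.025, estimated FDR = 0.98). The members furthest from 0, Cyp3a11 (1.53 ± 0.60) and Cyp2c55 (1.46 ± 0.63), did not pass. Cyp3a11 passed without knockout replicate 4 or wild type replicate 2 or 4 (0.014 to 0.043), and Cyp2c55 without knockout replicate 4 (0.0062). Without knockout replicate 4, 23 interferon-gamma genes rose, and 9 PPAR-alpha genes did without wild type replicate 1. The xenobiotic list (5 to 8 rose without knockout replicate 2 or 3 or wild type replicate 1 or 3) was not called with slide as a block (0.069) or without knockout replicate 3 or wild type replicate 1 or 3 (0.071 to 0.12). No list of other cell types was called, with medians from 0.03 for mast cells to 0.42 for stroma and muscle. T and NK cell markers (median 0.41, FDR = 0.18) were called without knockout replicate 4 (0.008) or wild type replicate 4 (0.021) or after normexp (0.038). Members that ran against their lists, named after their values were seen, were the risen Paneth list members Nod2 (0.79), Guca2b (0.79) and Fgfrl1 (0.70) and stem cell marker Msi1 (0.49). So were the fallen Arntl (-0.61) and Nfil3 (-0.89) of the clock and Acadl (-0.57) of the PPAR-alpha list.

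Between Tlr3 knockouts and wild type 8463 features differed, 5463 higher and 3000 lower. The median feature lay at 0.22, and the higher share of 64.6% was 48.7% under quantile normalization and 37.4% under median scaling. With slide as a block 9632 features and 11 of the 12 lists above were called (FDR up to 0.044). Of called features, chosen on the same slides, 97.3% to 99.8% kept direction within each. Called features numbered 2977 after normexp.

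In Tlr4 knockouts MHC class II genes rose, and enteroendocrine markers were lower as a list. Of MHC class II genes 7 of 8 rose (median 2.92, 2.78 to 3.14, FDR = 3.5e-08). H2-Aa (chromosome 17, 34421285 to 34421344, 4.31 ± 0.43, FDR = 5.1e-06) and the invariant chain Cd74 (chromosome 18, 60972075 to 60972132, 3.95 ± 0.43, FDR = 1.3e-05) changed most. Of enteroendocrine markers 12 of 28 fell and 2 rose (14 and 3 adjusted over the list alone, 13, 13 and 6 by scaling, median -0.42, -0.83 to -0.28, FDR = 3.6e-07, both estimated FDR = 0.39 to 0.51). The cholecystokinin gene Cck (-2.49 ± 0.31) and the ghrelin gene Ghrl (-2.22 ± 0.22) changed most. The other large rises were Zfp811 (5.31 ± 0.75), at least 9.47-fold, Lrmda (4.0 ± 0.25), the Wnt antagonist Sfrp1 (3.94 ± 0.41), at least 6.74-fold, and the heat shock genes Hspa1a (3.56 ± 0.51) and Hspa1b (3.36 ± 0.44). Then came Ceacam10 (3.51 ± 0.46), H2-DMb1 (3.36 ± 0.39) and Asap3 (3.36 ± 0.31), at least 4.52-fold (FDR up to 0.0001). The other large falls were the ferric reductase Cybrd1 (-5.36 ± 1.35), Ppp1r3g (-3.76 ± 0.52), at least 3.35-fold, Camk2b (-3.71 ± 0.24) and the duodenal transcription factor Pdx1 (-3.23 ± 0.95). Then came Vsig2 (-2.99 ± 0.26) (a second probe -0.18), Myom3 (-2.89 ± 0.17), Cpn2 (-2.71 ± 0.48), Pzp (-2.41 ± 0.68), at least 1.43-fold, and Bmp8b (-2.40 ± 0.46) (FDR up to 0.03). After normexp Cybrd1, Ppp1r3g, Pdx1, Bmp8b, Sfrp1 and Asap3 (FDR = 0.093 to 0.79) did not pass. The direction of Pzp (0.22, FDR = 0.79) turned. Pdx1 did not pass without knockout replicate 1, 2 or 4 or wild type replicate 2 or 4 (0.058 to 0.093). Pzp did not pass without knockout replicate 1, 2 or 3 or wild type replicate 1 or 4 (0.052 to 0.086), nor with slide as a block (0.06).

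Of interferon-stimulated genes 8 of 43 fell and 1 rose (18 and 1 adjusted over the list alone, 9, 13 and 1 by scaling, median -0.57, -1.08 to 0.02, FDR = 3.4e-07). Furthest from 0 were the risen Mx1 (1.32 ± 0.27) and the uncalled Oas2 (-1.29 ± 0.49), which passed without wild type replicate 2 (0.036). Of the list 1 fell without knockout replicate 1 or 2 or wild type replicate 4 (median then -0.32), 5 without wild type replicate 3 and 15 without knockout replicate 3. Of interferon-gamma response genes 3 of 31 rose (median 0.21, -0.01 to 0.57, FDR = 0.041, both estimated FDR = 0.98). Iigp1 (2.61 ± 0.68) and Gvin1 (1.43 ± 0.37) changed most. Of PPAR-alpha targets 5 of 27 rose (9 adjusted over the list alone, 8, 3 and 3 by scaling, median 0.33, -0.02 to 0.84, FDR = 0.0022). Angptl4 (2.77 ± 0.43) and Pdk4 (2.27 ± 0.51) changed most. Of goblet cell markers 2 of 24 fell (1 adjusted over the list alone, median -0.21, -0.39 to -0.15, FDR = 0.0051). The uncalled Retnlb (-1.78 ± 0.79) and the called Gcnt3 (-1.12 ± 0.26) were furthest from 0. Of tuft cell markers 1 of 22 fell (median -0.33, -0.57 to -0.21, FDR = 0.0051). The uncalled Alox5 (-0.87 ± 0.29) and Siglecf (-0.64 ± 0.36) were furthest from 0. Of cholesterol synthesis genes 2 of 24 fell (1 adjusted over the list alone, 3, 6 and 0 by scaling, median -0.23, -0.48 to -0.04, FDR = 0.00039, these 4 lists estimated FDR = 0.98). The uncalled Insig1 (-0.60 ± 0.20) was furthest from 0. Of the lists of other cells 2 were lower, and the others were not called (medians -0.22 to 0.14). Of T and NK cell markers 1 of 26 fell (0 adjusted over the list alone, median -0.28, -0.38 to -0.20, FDR = 0.009). The uncalled Ctsw (1.27 ± 0.68) and Prf1 (-0.95 ± 0.48) were furthest from 0. Of pancreatic enzymes 0 of 18 fell and 1 rose (3, 3 and 0 by scaling, median -0.29, -0.42 to -0.08, FDR = 0.017, both estimated FDR = 0.98). The uncalled Amy2a5 (-1.34 ± 0.47) and Cpa1 (-0.79 ± 0.40) were furthest from 0 and not well above background on any knockout array (Cpa1 at least 1.41-fold lower). Alpha-defensins (0 of 11 fell and 0 rose, median -0.33, FDR = 0.16) were not called as a list, with Defa39 (-1.0 ± 0.43) and Defa-rs12 (-0.66 ± 0.54) furthest from 0. Neither were other Paneth products (2 of 21 fell and 1 rose, median -0.11, FDR = 0.47), with Clps (-1.08 ± 0.33) and Mptx1 (-0.92 ± 0.64). Nor were antimicrobial genes (4 of 29 fell and 1 rose, 6, 6 and 0 by scaling, median -0.14, FDR = 0.1), with Saa3 (-2.0 ± 0.62) and Fut2 (-1.92 ± 0.40), or cell cycle genes (0 of 38 fell and 0 rose, median -0.14, FDR = 0.19). Clps (FDR = 0.037) did not pass with any 1 array but wild type replicate 4 left out (0.052 to 0.11). Nor did Saa3 (0.043) without knockout replicate 1, 2 or 4 or wild type replicate 1, 2 or 3 (0.054 to 0.13). Iigp1 did not pass without knockout replicate 3 or wild type replicate 2 or 3 (0.053 to 0.058), nor Gvin1 without wild type replicate 4 (0.058). Amy2a5 passed without wild type replicate 4 (0.032) and with slide as a block (0.037). After normexp Iigp1, Clps, Saa3 and Fut2 (FDR = 0.053 to 0.14) did not pass. The defensin list was called without knockout replicate 2 (0.013). The antimicrobial list was called without knockout replicate 1 (0.049) or without the filter (0.049), and the cell cycle list without knockout replicate 2 (0.033) or with Xist (0.032). After normexp all 4 of these lists were called (0.00026 to 0.029). Absorptive, proximal and xenobiotic genes were called without knockout replicate 4 (0.01 to 0.03). The interferon-gamma list was not called after normexp (FDR = 0.16), with slide as a block (0.056) or without knockout replicate 3 or wild type replicate 1, 2 or 3 (0.07 to 0.27), and its median was 0.33 without knockout replicate 2 and 0.43 without wild type replicate 4. The PPAR-alpha list was not called without knockout replicate 4 (0.15), nor the T and NK list without wild type replicate 4 (0.11), with medians of 0.08 and -0.14. Nor was the pancreas list without wild type replicate 3 (0.06) or after normexp (0.58, median 0.11 against 0.23 for all features). The few called members, named after their values were seen, were Plcg2 (-0.45) among tuft, Gzma (-0.94) among T and NK cell and Clca1 (-0.60) and Gcnt3 (-1.12) among goblet cell markers. Others were Lss (-0.49) and Srebf2 (-0.50) among cholesterol synthesis genes and the risen Ctrl (0.51) of the pancreas and Pax4 (1.41) and Pax6 (0.83) of the enteroendocrine list.

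Between Tlr4 knockouts and wild type 2785 features differed, 2114 higher and 671 lower. The higher share of 75.9% was 55.8% under median scaling. With slide as a block 2918 features and 9 of the 10 lists above were called (FDR up to 0.008). Of called features, chosen on the same slides, 99.3% to 99.9% kept direction within each. Called features numbered 664 after normexp and 4721 with array weights.

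In MyD88 knockouts interferon-stimulated genes fell and alpha-defensins rose. Of interferon-stimulated genes 32 of 43 fell (33 adjusted over the list alone, 33, 39 and 21 by scaling, median -0.83, FDR = 2.6e-18). Isg15 (-2.20 ± 0.31, FDR = 6.5e-05) and Trim30a (-2.10 ± 0.26, FDR = 2.5e-05) changed most. Of alpha-defensins 11 of 11 rose (4, 3 and 6 by scaling, median 1.20, FDR = 0.027, both estimated FDR = 0.43 to 0.57). Defa-rs12 (2.72 ± 0.54) and Defa22 (2.59 ± 0.55) changed most. Of MHC class II genes 7 of 8 rose (median 1.87, FDR = 0.016). H2-Aa (2.46 ± 0.43) and Cd74 (2.27 ± 0.43) changed most. Of the antimicrobial and mucosal defence list 7 of 29 fell and 4 rose (9, 12 and 6 by scaling, median -0.13, FDR = 0.003, both estimated FDR = 0.43 to 0.45). Retnlb (-5.60 ± 0.79) and Saa2 (-4.87 ± 0.66) changed most. Saa3 (-4.63 ± 0.62), Saa1 (-4.14 ± 0.55), Cpn2 (-4.56 ± 0.48) and B3galt5 (-4.40 ± 0.54) were also among the 10 largest falls, with Lrg1 (-3.71 ± 0.53), Gml (-4.21 ± 0.46) and the aryl hydrocarbon receptor target Cyp1a1 (-4.46 ± 0.79) (FDR up to 0.00034). The largest fall of all was Xist (-9.62 ± 2.19, FDR = 0.0021). With these groups 3 marker lists of other cells were higher. Of B and plasma cell markers 9 of 15 rose (10 adjusted over the list alone, 8, 8 and 0 by scaling, median 1.06, FDR = 0.031). Cr2 (2.24 ± 0.33) and Ms4a1 (2.14 ± 0.53) changed most. Of mast cell markers 8 of 10 rose (5, 5 and 3 by scaling, median 1.48, FDR = 0.037). Mcpt1 (2.45 ± 0.62) and Cd200r3 (2.43 ± 0.47), at least 1.95-fold higher, changed most. Of red blood cell genes 4 of 5 rose (median 0.78, FDR = 0.039, these 3 lists estimated FDR = 0.43 to 0.45). Hba-a1 (1.80 ± 0.23) and Hba-a2 (1.54 ± 0.19) changed most. Stroma and muscle (median 0.73, FDR = 0.19) and endothelial markers (median 0.81, FDR = 0.13) were not called as lists, the first except without the filter (0.046). The largest rises were the Y-linked Eif2s3y (10.59 ± 2.29), Ddx3y (7.94 ± 1.83), Kdm5d (6.97 ± 1.53) and Uty (5.32 ± 1.10), at least 333-, 52.9-, 44.8- and 9.69-fold. Then came Mrgpra2b (4.92 ± 0.63) and Ssty1 (4.79 ± 0.74), at least 6.57- and 6.31-fold (Ssty1 on 3 of 4 arrays). Dlx5 (4.70 ± 0.64), Rab11fip5 (4.62 ± 0.49) (a second probe 0.66), Fam186b (4.52 ± 0.61) and Ceacam10 (4.52 ± 0.46) completed the 10 (FDR up to 0.0023). With Xist Eif2s3y, Ddx3y, Kdm5d, Uty, Ms4a1 and Mcpt1 (FDR = 0.051 to 0.95) did not pass. After normexp Mrgpra2b, Ssty1, Cr2, Ms4a1 and Cd200r3 (FDR = 0.058 to 0.7) did not. The defensin list was not called without knockout replicate 3 (0.066). Without that array 6 alpha-defensins rose, and without wild type replicate 4 only 5 did and the interferon-stimulated median was -0.51. With Xist 5 mast cell genes rose and the antimicrobial median was -0.25. Mast cell markers were not called without knockout replicate 3 (0.064), with Xist (FDR = 0.094), after normexp (0.074) or under quantile normalization (0.11). B and plasma cell markers were not called in the last 3 settings (0.098, 0.14 and 0.071). Nor were red blood cell genes (0.098, 0.053 and 0.071), or without knockout replicate 3 (0.052) or wild type replicate 1 (0.05). MHC class II was not called with Xist (0.094).

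Enterocyte lists were lower in MyD88 knockouts, with mast cell markers (median 1.48) and Y-linked genes higher. Lists were tested against all features (median 0.30), unmatched for signal. Of absorptive enterocyte genes 19 of 36 fell and 3 rose (21 and 3 adjusted over the list alone, 24, 28 and 10 fell and 0, 0 and 0 rose by scaling, median -0.58, FDR = 1.2e-08, estimated FDR = 0.45). The uncalled Akp3 (-2.76 ± 1.18) and the apolipoprotein Apob (-2.15 ± 0.21) were furthest from 0. Akp3 passed without knockout replicate 1 (0.047) or wild type replicate 1 (0.049). Of proximal genes 8 of 22 fell and 3 rose (9 and 3 adjusted over the list alone, 10, 13 and 5 by scaling, median -0.55, FDR = 0.00061). The risen Gkn3 (2.48 ± 0.48) and the uncalled Cybrd1 (-2.25 ± 1.35) were furthest from 0. Of ileal genes 3 of 19 fell and 1 rose (5, 9 and 2 by scaling, median -0.16, FDR = 0.0066). The uncalled Slc6a14 (-1.38 ± 0.63) (a second probe -5.25) and Fgf15 (-1.28 ± 0.60) were furthest from 0. Of xenobiotic metabolism genes 8 of 32 fell and 1 rose (8 and 0 adjusted over the list alone, 8, 14 and 4 by scaling, median -0.16, FDR = 0.00087, these 3 lists estimated FDR = 0.43 to 0.57). Cyp1a1 and Cyp2b10 (-2.03 ± 0.43) changed most. Of clock genes 7 of 20 fell and 3 rose (8, 14 and 5 fell and 2, 0 and 2 rose by scaling, median -0.36, FDR = 0.00032). Dbp (-2.40 ± 0.42) and Ciart (-2.17 ± 0.55) changed most. Of cholesterol synthesis genes 5 of 24 fell and 1 rose (3 and 1 adjusted over the list alone, 5, 18 and 2 by scaling, median -0.24, FDR = 0.00078, both estimated FDR = 0.43 to 0.45). Stard4 (-1.28 ± 0.19) (other probes -0.16 and -0.13) and Insig1 (-0.88 ± 0.20) changed most. Of stress response genes 10 of 24 fell and 1 rose (9, 19 and 6 by scaling, median -0.21, FDR = 9.2e-05). Chac1 (-1.38 ± 0.43) and Trib3 (-0.98 ± 0.25) changed most. Of interferon-gamma response genes 9 of 31 fell and 2 rose (10, 17 and 3 by scaling, median -0.28, FDR = 0.0021, both estimated FDR = 0.43 to 0.45). The risen Gvin1 (1.73 ± 0.37) and the uncalled Cxcl10 (-1.18 ± 0.57) were furthest from 0. Of immediate early and heat shock genes 6 of 28 fell and 5 rose (5 and 4 adjusted over the list alone, 6, 15 and 4 fell and 3, 1 and 0 rose by scaling, median -0.17, FDR = 0.0069). Atf3 (-2.23 ± 0.49) and the risen Hspa1a (1.42 ± 0.51), which did not pass without knockout replicate 2 or 3 or wild type replicate 1 (0.073 to 0.097), changed most. Of NF-kappaB targets 7 of 31 fell and 9 rose (9, 14 and 6 fell and 6, 4 and 2 rose by scaling, median -0.08, FDR = 0.044, both estimated FDR = 0.45). Il1a (2.43 ± 0.30), at least 1.34-fold higher on 3 of 4 arrays, and Il18 (-1.69 ± 0.21) were furthest from 0. Of Toll-like receptor pathway genes 11 of 36 fell and 8 rose (12 and 9 adjusted over the list alone, 11, 20 and 2 fell and 6, 3 and 1 rose by scaling, median 0.00, FDR = 0.016, estimated FDR = 0.43), with a mean of 0.08. The risen Tlr5 (2.24 ± 0.34) and Nod2 (1.51 ± 0.22) changed most. The NF-kappaB list was not called without knockout replicate 2 or 4 or wild type replicate 1 or 2 (0.053 to 0.079), without the filter (0.053) or under quantile normalization (0.13). Under the latter the pathway (0.095), heat shock (0.067) and ileal (0.05) lists were not called either, nor was the pathway list after normexp (0.053). After normexp Il1a, Tlr5, Nod2, Ciart and Hspa1a (FDR = 0.053 to 0.78) did not pass. Nor did Chac1, Ciart and Hspa1a (FDR = 0.12 to 0.42) with Xist, when 4 xenobiotic, 6 stress and 9 heat shock genes fell and ileal (-0.50), clock (-0.67) and heat shock (-0.39) medians moved. Medians also moved without knockout replicate 2 (ileal -0.06, xenobiotic -0.05, interferon-gamma -0.14) or 3 (ileal -0.28, clock -0.58). They did without wild type replicate 1 (ileal -0.36, xenobiotic -0.28), 2 (xenobiotic -0.03) or 4 (interferon-gamma -0.14, heat shock -0.06), and 2 cholesterol genes fell without wild type replicate 1 or 2. Other Paneth products (11 of 21 rose and 2 fell, 12 and 2 adjusted over the list alone, 11, 5 and 6 by scaling, median 0.94, FDR = 0.3) were called only after normexp (0.02), with the angiogenin Ang4 (2.46 ± 0.67) and the intelectin Itln1 (1.76 ± 0.53) changed most. With Xist Ang4 and Itln1 (FDR = 0.13 to 0.14) did not pass. Cell cycle genes (0 of 38 fell and 1 rose, median 0.32, FDR = 0.9) were called only with Xist (0.00024, 23 rose, median 1.08). Tuft cell markers (median -0.07, FDR = 0.076) were called without knockout replicate 4 or wild type replicate 2 or 3 (0.041 to 0.046) and with Xist (0.0017). Stem cell markers (median 0.53, FDR = 0.37) were called with Xist (0.0043, median 0.90) and after normexp (0.015), and goblet markers with Xist (0.027).

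Between MyD88 knockouts and wild type 10815 features differed, 8097 higher and 2718 lower. The median feature lay at 0.30, and the higher share of 74.9% was 59.2% under quantile normalization and 34.8% under median scaling. The weakest of 4 groups of features by wild type signal changed by a median of 0.97 and the strongest by -0.04 (0.47 and 0.14 in Tlr3 knockouts, 0.31 and 0.18 in Trif mutants, 0.10 and -0.02 in Tlr4 knockouts). Called features numbered 2865 after normexp.

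**Figure D4:**
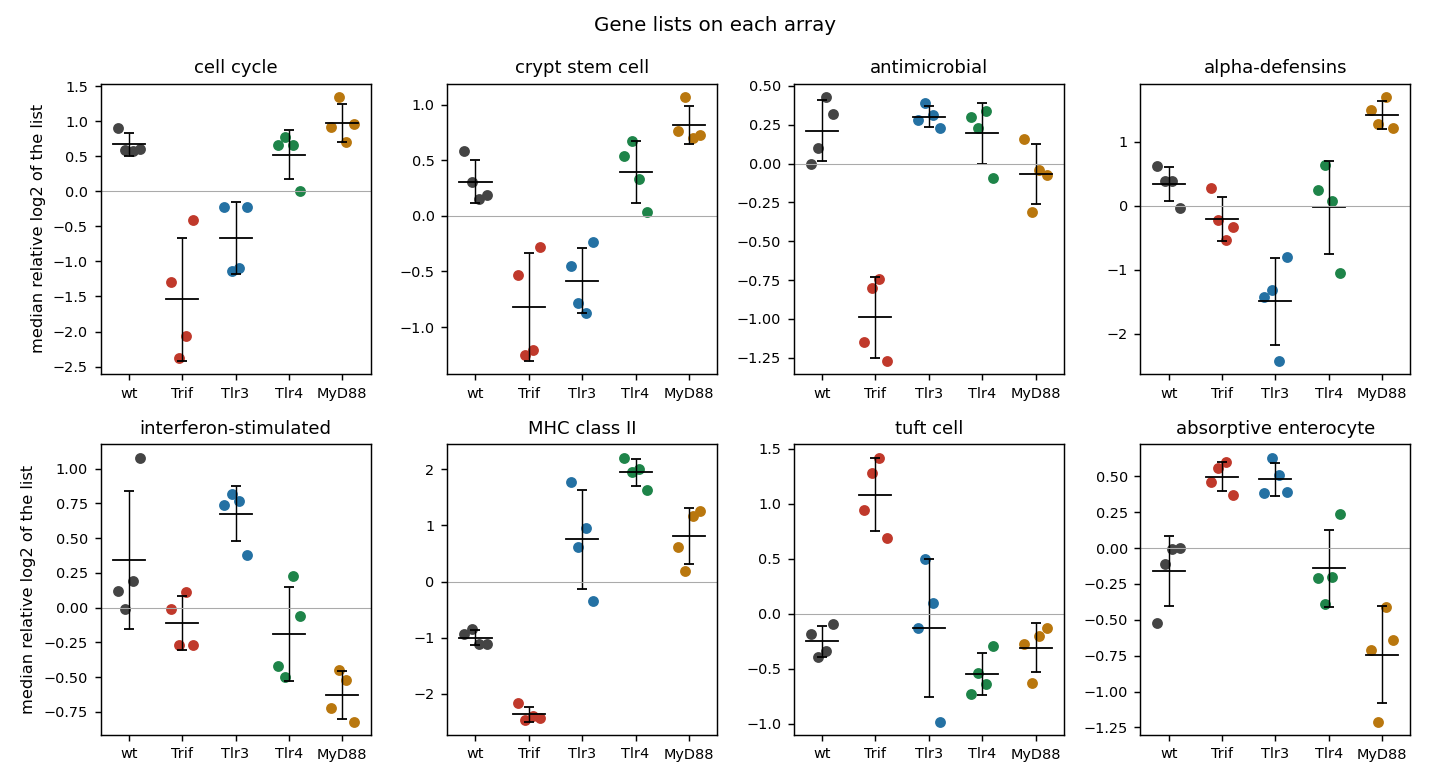
Median over each list of log2 signal relative to the gene's mean over 20 arrays (vertical axes), for 8 gene lists on each array by genotype (horizontal axes), with the mean and SD of 4 arrays. The cell cycle list averages -1.54 in Trif mutants, -0.66 in Tlr3 knockouts and 0.67 in wild type.

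Between Trif mutants and Tlr3 knockouts 4416 features differed, 2181 higher and 2235 lower in Trif mutants (49.4% higher, 67.4% under median scaling). Higher in Trif mutants were Defa21 (13.71 ± 0.40, FDR = 3.7e-13), at least 3390-fold, and Tlr3 (7.15 ± 0.14), at least 30.5-fold. Then came Defa39 (4.40 ± 0.43), Apcdd1 (3.94 ± 0.26) (another probe -0.06) and Plscr4 (3.27 ± 0.59), at least 4.36-fold (after normexp 1.19, FDR = 0.13). Lower were Saa3 (-9.05 ± 0.62, FDR = 6.8e-08), at least 309-fold, Saa2 (-9.0 ± 0.66), Saa1 (-6.01 ± 0.55), Pla2g5 (-5.50 ± 0.49) and Naip5 (-5.52 ± 1.67). Naip5 did not pass without Tlr3 knockout replicate 1, 2, 3 or 4 or Trif mutant replicate 2 or 3 (0.052 to 0.096), with only these genotypes (0.17) or with Xist (0.14). Lower in Trif mutants were the lists of MHC class II (7 of 8 lower, median -3.20, -3.94 to -2.11, FDR = 2.6e-07), interferon-stimulated (28 of 43 lower and 1 higher, 32 and 1 adjusted over the list alone, 28, 21 and 15 by scaling, median -0.75, -0.92 to -0.61, FDR = 1.9e-10), interferon-gamma response (median -0.77, -1.01 to -0.16, FDR = 4.8e-07) and antimicrobial genes (16 of 29 lower and 4 higher, 19 and 4 adjusted over the list alone, 16, 14 and 10 lower and 4, 4 and 0 higher by scaling, median -1.29, -1.33 to -0.82, FDR = 4.3e-07). So were cell cycle (median -0.90, -1.41 to -0.23, FDR = 2.6e-07), cholesterol synthesis (median -0.69, -0.95 to -0.13, FDR = 7.9e-05), stress response (median -0.30, -0.45 to -0.11, FDR = 0.0059) and stromal genes (5 of 23 lower and 1 higher, 6 and 1 adjusted over the list alone, 4, 3 and 1 by scaling, median -0.48, -0.75 to -0.07, FDR = 0.044). Higher were tuft (median 1.19, 0.77 to 1.88, FDR = 2.9e-10) and enteroendocrine markers (median 0.71, 0.46 to 0.81, FDR = 4.7e-09), alpha-defensins (8 of 11 higher and 2 lower, 7, 8 and 2 by scaling, median 1.36, 0.26 to 1.96, FDR = 0.001) and xenobiotic metabolism genes (median 0.46, -0.26 to 1.01, FDR = 0.0017). These 12 lists had estimated FDR = 0.093 to 0.78. The cell cycle median was -0.57 without Trif mutant replicate 2 and -0.38 with Xist, and the xenobiotic one 0.28 without Tlr3 knockout replicate 4. Only 5 alpha-defensins were higher without Trif mutant replicate 1 or Tlr3 knockout replicate 3. Stromal markers were not called without Tlr3 knockout replicate 1 or 4 or Trif mutant replicate 2 or 4 (0.068 to 0.11), with median -0.25 in the first case, nor after normexp (0.57), when xenobiotic genes were not either (0.67). Goblet, T and NK and NF-kappaB lists were called without Tlr3 knockout replicate 4 (0.048, 0.024 and 0.01), and the first without Trif mutant replicate 3 (0.047). With slide as a block these 12 lists (FDR up to 0.038) and 4904 features were called, after normexp 1222 and with only these genotypes 2931.

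Between Trif mutants and Tlr4 knockouts 8936 features differed, 5048 higher and 3888 lower in Trif mutants (median feature 0.12). Sex was unequal. Higher were Eif2s3y (8.40 ± 2.29, FDR = 0.0071) and Ddx3y (6.84 ± 1.83), at least 71.4- and 24.5-fold on 3 of 4 arrays, Ppp1r3g (5.39 ± 0.52), at least 10.4-fold, Afm (4.79 ± 0.26) (another probe 0.54) and Zmat4 (4.02 ± 0.29) (another 0.71). Lower were Xist (-8.04 ± 2.19, FDR = 0.007), Pla2g5 (-7.13 ± 0.49), Saa2 (-7.09 ± 0.66), Saa3 (-6.93 ± 0.62), at least 71.5-fold, and Retnlb (-6.10 ± 0.79). With Xist Eif2s3y and Ddx3y (FDR = 0.76 to 0.92) did not pass and 5499 features were called. MHC class II (7 of 8 lower and 1 higher, median -4.30, -4.55 to -4.02, FDR = 2.1e-06), cell cycle (median -2.03, -3.29 to -0.44 on slide 4, FDR = 2.5e-19) and stem cell genes (median -1.12, -1.98 to -0.39, FDR = 7.6e-06) were lower as lists. So were antimicrobial (16 of 29 lower and 4 higher, 17 and 5 adjusted over the list alone, median -1.08, -1.20 to -1.07, FDR = 5.3e-05), interferon-gamma response (median -0.41, -0.69 to -0.24, FDR = 0.0092) and stress response genes (median -0.32, -0.57 to -0.27, FDR = 0.0029). Higher were tuft (median 1.70, 0.95 to 2.24, FDR = 1.4e-08) and enteroendocrine markers (median 0.95, 0.75 to 1.08, FDR = 8.2e-05), absorptive (median 0.66, 0.14 to 0.93, FDR = 1.2e-05) and xenobiotic metabolism genes (median 1.15, 0.53 to 1.63, FDR = 5.3e-05) and, among other cells, T and NK cell markers (10 of 26 higher and 1 lower, 11, 10 and 3 by scaling, median 0.50, 0.34 to 0.70, FDR = 0.024). These 11 lists had estimated FDR = 0.35 to 0.85. With Xist the cell cycle and stem cell medians were -1.26 and -0.74. T and NK cell markers were not called with Xist (FDR = 0.11, 4 higher) or without Trif mutant replicate 1 (0.059) or 4 (0.092). PPAR-alpha (median 0.24, FDR = 0.38) and proximal genes (median 0.54, FDR = 0.15) were called without Tlr4 knockout replicate 4 (0.016 and 0.034). With slide as a block these 11 lists (FDR up to 0.042) and 9627 features were called, and after normexp 3702.

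Between Trif mutants and MyD88 knockouts 14037 features differed, 5929 higher and 8108 lower in Trif mutants (median feature -0.19, 42.2% higher, 58.9% under median scaling). Genotype and scan day cannot be told apart. Higher were the tight junction gene Cldn4 (4.47 ± 0.61, FDR = 9.6e-06), Zmat4 (3.86 ± 0.29) (another probe 1.18), Lifr (3.74 ± 0.58) (others -1.26 and -0.81), the clock gene Dbp (3.66 ± 0.42) and Nyap1 (3.63 ± 0.29). Lower were the trefoil peptide Tff2 (-6.63 ± 1.39, FDR = 0.00055), at least 50.5-fold, Pla2g5 (-5.90 ± 0.49), Ceacam10 (-5.39 ± 0.46), Olfm4 (-5.24 ± 0.58) and Tlr2 (-4.93 ± 0.36). Cell cycle (median -2.49, FDR = 2.8e-11), stem cell (median -1.69, FDR = 0.00032), MHC class II (7 of 8 lower, median -3.15, FDR = 0.0031) and alpha-defensin genes (11 of 11 lower, median -1.79, FDR = 0.0031) were lower as lists, as were other Paneth products (13 of 21 lower and 3 higher, median -1.51, FDR = 0.037) and B and plasma cell markers (11 of 15 lower, 12 adjusted over the list alone, 11, 11 and 0 by scaling, median -1.01, FDR = 0.013). Absorptive (median 1.30, FDR = 4.2e-11), xenobiotic metabolism (median 1.44, FDR = 9.5e-08), tuft (median 1.35, FDR = 3.8e-06) and interferon-stimulated genes (24 of 43 higher and 3 lower, 25 and 3 adjusted over the list alone, 17, 28 and 14 by scaling, median 0.51, FDR = 0.00084) were higher. So were clock (median 0.92, FDR = 0.0012), PPAR-alpha (median 0.47, FDR = 0.0031), proximal (median 0.83, FDR = 0.011), ileal (median 0.86, FDR = 0.0031) and heat shock genes (median 0.56, FDR = 0.024). These 15 lists had estimated FDR = 0.52 to 0.56. The proximal median was 0.53 without Trif mutant replicate 4. Other Paneth products were not called with Xist (0.055) or without MyD88 knockout replicate 3 (0.1) or Trif mutant replicate 4 (0.075), and heat shock genes without MyD88 knockout replicate 1 (0.053) or under quantile normalization (0.12). Nor were PPAR-alpha genes in the last setting (0.065). Antimicrobial genes were called in it (0.015), after normexp (0.0076) and without MyD88 knockout replicate 4 (0.045) or Trif mutant replicate 3 (0.037), and endothelial markers without Trif mutant replicate 3 (0.029). After normexp 7103 features were called, but not the B and plasma cell, interferon-stimulated, heat shock, ileal, proximal and PPAR-alpha lists (FDR = 0.11 to 0.81).

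Between MyD88 and Tlr4 knockouts 10432 features differed, 7180 higher and 3252 lower in MyD88 knockouts (median feature 0.24). The higher share of 68.8% was 56.8% under quantile normalization and 40.2% under median scaling, and genotype and scan day cannot be told apart. Higher were Eif2s3y (10.51 ± 2.29), Gkn2 (8.41 ± 1.75), Ddx3y (7.84 ± 1.83), Kdm5d (7.20 ± 1.53) and Tff2 (7.0 ± 1.39), at least 308-, 244-, 49-, 41.5- and 57.2-fold. Lower were Xist (-10.40 ± 2.19), Retnlb (-3.82 ± 0.79), Tsix (-3.65 ± 0.92), Cap1 (-3.33 ± 0.22) and the ubiquitin-like Ubd (-3.27 ± 0.39) (FDR up to 0.0048). With Xist Eif2s3y, Ddx3y, Kdm5d, Tsix, Gkn2 and Retnlb (FDR = 0.057 to 0.84) did not pass. Nor did Tff2 and Tsix (FDR = 0.053 to 0.16) after normexp. Interferon-stimulated (15 of 43 lower and 1 higher, 17, 25 and 9 by scaling, median -0.48, FDR = 4.2e-07), interferon-gamma response (median -0.50, FDR = 4.1e-06), MHC class II (7 of 8 lower and 1 higher, 7, 7 and 4 by scaling, median -1.32, FDR = 0.0066) and antimicrobial genes (7 of 29 lower and 5 higher, median -0.22, FDR = 0.032) were lower as lists. So were absorptive (median -0.55, FDR = 8.5e-08), clock (median -0.63, FDR = 4e-05), xenobiotic (median -0.30, FDR = 0.00076), PPAR-alpha (median -0.39, FDR = 0.002) and ileal genes (median -0.43, FDR = 0.00087). The stress (median -0.36, FDR = 1.2e-05), heat shock (median -0.38, FDR = 0.00076), Toll-like receptor pathway (median -0.08, FDR = 0.012) and proximal lists (median -0.14, FDR = 0.021, mean 0.06) were lower too. Higher were enteroendocrine markers (median 0.82, FDR = 4e-05) and alpha-defensins (10 of 11 higher, median 1.37, FDR = 0.0015). Together with them were B and plasma cell (9 of 15 higher, 10 adjusted over the list alone, 7, 8 and 0 by scaling, median 0.87, FDR = 0.023), endothelial (10 of 14 higher, 7, 7 and 0 by scaling, median 1.08, FDR = 0.0071), pancreatic (12 of 18 higher, 13 adjusted over the list alone, 10, 9 and 0 by scaling, median 0.71, FDR = 0.0044), red blood cell (5 of 5 higher, 3, 3 and 1 by scaling, median 1.15, FDR = 0.011) and mast cell genes (7 of 10 higher, 6, 7 and 0 by scaling, median 1.49, FDR = 0.022). These 20 lists had estimated FDR = 0.35 to 0.57. B and plasma cell markers were not called without Tlr4 knockout replicate 4 (0.066). Nor were antimicrobial genes without MyD88 knockout replicate 2 or Tlr4 knockout replicate 1 or 2 (0.052 to 0.057) or xenobiotic genes without Tlr4 knockout replicate 4 (0.067). Without Tlr4 knockout replicate 4 the xenobiotic median was 0.02, the PPAR-alpha one -0.15, the clock one -0.30 and the pathway one -0.20. Without MyD88 knockout replicate 2 the first 2 were -0.16 and -0.25, and without Tlr4 knockout replicate 3 the interferon-gamma median was -0.32. With Xist the ileal, heat shock and proximal medians were -0.77, -0.69 and -0.32, and 4 antimicrobial and 3 MHC class II genes were lower and 5 endothelial, 6 pancreatic and 2 red blood cell genes higher. Then the B and plasma cell, mast cell and proximal lists were not called (0.076 to 0.12). Nor, under quantile normalization, were these or the endothelial and antimicrobial lists (0.053 to 0.082), nor MHC class II (0.1) and antimicrobial genes (0.068) without the filter. After normexp 2410 features were called, but not the 5 lists of other cells nor the antimicrobial, xenobiotic, PPAR-alpha, pathway and proximal lists (FDR = 0.052 to 0.77). Other Paneth and stromal lists were called without MyD88 knockout replicate 4 (0.015 and 0.049).

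Trif mutants and Tlr3 knockouts shared 3567 higher and 2174 lower features, and 119 moved in opposite directions. Independent lists would share 1552, 475 and 1718, and unchanged groups simulated against the same wild type arrays shared at most 0. With wild type arrays split 2 and 2, so no control was shared, 2064 higher and 1412 lower features were shared on average (independent 829 and 269). The covariance of their log2 changes was 0.38, against 0.041 simulated. Tlr3 and Tlr4 knockouts shared 1684 higher and 209 lower (independent 524 and 93, split controls 1050 and 70). For Trif mutants and Tlr4 knockouts they were 1400 and 164 (599 and 106, 837 and 49). With MyD88 knockouts the numbers were 1920 and 359 for Trif mutants (2280 and 430, 1069 and 198). They were 2102 and 286 for Tlr3 (1995 and 375, 1118 and 136) and 1294 and 287 for Tlr4 (770 and 84, 730 and 100). With split controls independent lists would share 248 and 32, 308 and 42, 1263 and 250, 1017 and 192 and 371 and 28. In the order of these 5 pairs, 39, 242, 1960, 1581 and 127 features moved in opposite directions (independent 457, 524, 2040, 1781 and 509). In all 4 genotypes 751 features lay above and 42 below wild type (independent 55.2 and 1.8, split controls not run).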

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

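The tests on alpha-defensins, cell cycle genes and more cells of other types were chosen after the result was seen, and the test on weak features before. In 45 of 725 groups of 4 arrays, 1 array stood apart from the other 3 by more than Dixon's 95% limit, where chance gives about 1 in 20. The value of that array is given as log2 signal relative to the array's 75th percentile, or, for a list, the median over its genes of log2 signal relative to the gene's mean over 20 arrays, with the other 3 in parentheses. On Tlr4 knockout replicate 4 it was Gzma 2.27 (1.5 to 1.61), Pdk4 2.75 (0.49 to 0.73), Pla2g5 1.12 (2.47 to 2.71), the enteroendocrine list -0.29 (-0.47 to -0.44), the PPAR-alpha list 0.58 (-0.13 to -0.08), the cell cycle list 0.00 (0.66 to 0.78) and the proximal list 0.21 (-0.39 to -0.36). On replicate 3 it was Gbp6 -1.05 (-2.27 to -2.13), Tlr3 -1.38 (-1.74 to -1.70) and Ubd 4.17 (3.1 to 3.17). Replicate 1 had Lrmda -1.17 (-1.79 to -1.69), and replicate 2 Xist 2.99 (2.75 to 2.78). On wild type replicate 4 it was Afm -3.99 (-4.42 to -4.38), Ceacam10 -6.80 (-4.61 to -4.18), Gbp3 1.47 (-0.81 to -0.47), Gpc3 -2.15 (-1.27 to -1.11), Rtp4 5.02 (3.89 to 4.0) and the T and NK cell list 0.29 (-0.24 to -0.22). On replicate 1 it was Mrgpra2b -9.05 (-8.36 to -8.33), the cell cycle list 0.91 (0.57 to 0.61), the proximal list -0.47 (0.00 to 0.07) and the suckling-type list -0.39 (-0.05 to -0.01). Replicate 2 had Cpn2 -0.03 (1.06 to 1.27) and Myd88 1.94 (2.17 to 2.21), and replicate 3 Cr2 -4.35 (-4.73 to -4.68) and Ctsw -6.15 (-1.96 to -1.66). Trif mutant replicate 4, the only Trif array with Xist signal, had Ddx3y -8.04 (0.53 to 0.58), Eif2s3y -8.09 (2.59 to 2.68), Srd5a2 -6.56 (-4.40 to -4.13), Ticam1 1.60 (2.10 to 2.18), Uty -7.98 (-2.99 to -2.69) and Xist 2.26 (-8.07 to -7.41). Replicate 3 had the B and plasma cell list -0.02 (-0.50), the cholesterol synthesis list 0.26 (-0.36 to -0.30) and the stress response list 0.05 (-0.24 to -0.20). Replicate 1 had the NF-kappaB list -0.21 (-0.04 to -0.01). On MyD88 knockout replicate 2 the value was Fabp6 1.85 (2.97 to 3.16), Jchain -3.13 (-2.52 to -2.46), Nyap1 -2.59 (-1.60 to -1.45), Rab11fip5 -3.13 (-0.52 to 0.00) and the stem cell list 1.07 (0.70 to 0.76). On replicate 1 it was Myd88 1.02 (0.80). On Tlr3 knockout replicate 2 it was Adh1 6.98 (6.47 to 6.55) and Mx1 -1.90 (-1.49 to -1.44), and on replicate 4 Ido1 1.55 (3.85 to 4.09).

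In Tlr3 knockouts alpha-defensin probes switched between bright and background, with Defa21 at -14.55 and Defa-rs2 at 13.60. Fewer Paneth cells would raise no alpha-defensin, so the rise of 13.60 (adjusted p = 8.5e-11) argues against them as the cause of this switch. Other alleles of a chromosome 8 segment that came with the Tlr3 mutation are a candidate explanation: other called features changed at least 4-fold were 6 of 154 between the defensins and Tlr3 (22166004 to 46482068) and 263 of 21538 elsewhere, an odds ratio of 3.28 (95% interval 1.17 to 7.4, Fisher's exact p = 0.013). Whether fewer Paneth cells lowered the other Paneth genes (median -0.63) stays open, with an adjusted p of 0.91 under an estimated correlation. An effect of Tlr3 itself was not tested and stays open.

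Cell cycle genes were lower in Trif mutants and Tlr3 knockouts. Fewer isolated crypts would lower other Paneth genes alike. In Trif mutants their median lay 1.71 above that of the cell cycle genes (SD of their changes 1.14), but stem cell markers fell too (median -1). In Tlr3 knockouts it lay 0.66 above (SD 1.0), which leaves this open in both. With Xist the cell cycle median was -1.53 in Trif mutants (33 of 38 fell) and -1.10 in Tlr3 knockouts (36 of 38), which argues against sex as the whole cause in Tlr3 knockouts and leaves a part of it open in Trif mutants. Slower crypt cell division may explain this too and was not tested.

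Of 7 marker lists of other cells 3 were called higher in MyD88 knockouts, up to a median of 1.48 for mast cells, although the cells had been separated from immune cells. More cells of all other types would raise all 7. T and NK cells (mean 0.20 ± 0.10, median 0.07, 5 of 26 rose) were not clearly below all features (median 0.30). A rise of all types or of single ones stays open. Weak features lay higher here, 0.97, 0.49, 0.11 and -0.04 from the weakest to the strongest of 4 groups by wild type signal, but also in Tlr3 knockouts of the first scan day (0.47 to 0.14), and ranking by the subtracted signal raises the weakest group by itself. Only 2 of the 7 lists, B and plasma cells and mast cells, lay in the upper 2.5% of 10000 random lists of matched signal, so a dependence on signal may account for 4 others but not for T and NK cells, which lay below the median of theirs (0.31). Scan day and genotype cannot be told apart.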

How the results depend on the processing

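Fits with Xist as a covariate, without X and Y features, over scan day 1 alone and, for lists, with slide as a block were chosen after the data were seen. Of 348 changes of named genes under 36 settings, 204 kept direction and side of the threshold throughout. Of their 8112 values 7698 did so, 280 kept direction but no longer passed, 118 passed newly and 16 turned. Normexp ended 69 calls and the Xist covariate 39 without turning them. Called features by comparison, in the order Trif, Tlr3, Tlr4 and MyD88 against wild type, Trif against Tlr3, Tlr4 and MyD88, and MyD88 against Tlr4, numbered 5161, 2977, 664, 2865, 1222, 3702, 7103 and 2410 after normexp and 3240, 2711, 1296, 4095, 1266, 2930, 6622 and 3983 with a log2 change of at least 1. With Xist they were 6311 for Trif mutants against wild type and 5499 against Tlr4 knockouts, with array weights 4721 for Tlr4 knockouts, and with only the genotypes compared 2931 for Trif mutants against Tlr3 knockouts. All other counts lay within 1.5 times. The median of all features moved to 0.54, 0.23, 0.23, 0.19, 0.29, 0.32, 0.40 and -0.09 after normexp, 0.08, 0.05, -0.03, 0.11, -0.01, 0.07, -0.06 and 0.12 under quantile normalization and 0.08, -0.01, -0.11, -0.10, 0.06, 0.14, 0.09 and -0.04 under median scaling. Leaving out 1 array gave 8182 to 9951, 6536 to 8426, 2094 to 2578, 9016 to 10410, 3238 to 4598, 7545 to 9209, 12899 to 14097 and 8373 to 10247 features, and 11 to 14, 11 to 15, 8 to 12, 15 to 19, 11 to 14, 10 to 13, 14 to 17 and 18 to 22 lists.

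With camera's estimated correlation 0 lists were called in each comparison, and 2, 0, 2, 3, 3, 2, 0 and 2 had an unadjusted p under 0.05. Normexp called 19 lists between Trif mutants and Tlr3 knockouts, against 12, and quantile normalization 11 for MyD88 knockouts, against 18. Over the alternatives with the preset correlation list calls were lost 12, 4, 10, 24, 6, 3, 12 and 25 times and gained 11, 12, 15, 10, 16, 2, 6 and 12 times. With the wild type arrays split, shared changes numbered 3476 for Trif and Tlr3, 886 for Trif and Tlr4, 1267 for Trif and MyD88, 1120 for Tlr3 and Tlr4, 1254 for Tlr3 and MyD88 and 830 for Tlr4 and MyD88, where each comparison rests on fewer arrays. Within 5 Mb of the targeted gene the odds ratio of called features was 0.647 (Fisher's exact p = 0.057) for Trif mutants and turned to 1.05 (p = 0.82) for Tlr4 knockouts.

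With the replicate block 9768, 8493, 2740, 10863, 4366, 8990, 14168 and 10457 features were called. In Tlr4 knockouts it ended the call of Reg2 (-1.87, adjusted p = 0.062), made those of Tpsg1 (-0.56, 0.014) and 2210010C04Rik (-0.73, 0.042) and changed no other call of a gene or list reported here. Elsewhere it changed those of Cyp2a5, Jchain and, in Trif mutants, goblet markers (adjusted p = 0.037). Only wild type and Tlr4 knockouts had all pairs over 0.1, and there all 8 arrays correlated best with their own number, against 7 of 8 for wild type and Trif mutants and 0 to 6 for other pairs of genotypes.

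The 16 turned values were, after normexp, Ifit2 in Trif mutants (0.03) and in Tlr4 knockouts Tlr3 (0.01), Tlr4 (0.46), Pzp (0.22), Hpgds (0.36), Prf1 (0.32), Amy2a5 (0.40) and Cpa1 (0.39). Under quantile normalization Epb42 in MyD88 knockouts turned (-0.21), under median scaling Myd88 in Tlr3 knockouts (-0.06), and Myd88 in Tlr4 knockouts with array weights (0.03) or without Tlr4 knockout replicate 4 (0.01, from -0.09 over left-out arrays). With Xist Ddx3y turned in MyD88 knockouts against wild type (-0.03), and against Tlr4 knockouts Eif2s3y (-0.24), Ddx3y (-0.78) and Tsix (0.60). The cause was not tested for these values, nor for the moved counts, except that a log2 change of at least 1 is a higher bar by construction. Signal over background limits the weak features.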

Other observations

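Some uncalled lists of gut development held many called genes. Of genes of the suckling-period enterocyte 7 of 15 rose and 2 fell in Trif mutants (5, 5 and 3 by scaling, median 0.38, FDR = 0.39) and 8 rose and 2 fell in Tlr3 knockouts (5, 3 and 3 by scaling, median 0.46, FDR = 0.28), and of genes of the weaned enterocyte 6 of 10 rose and 1 fell (3, 5 and 2 by scaling, median 0.65, FDR = 0.39) and 4 rose and 2 fell (1, 2 and 2 by scaling, median 0.54, FDR = 0.97). Of macrophage, dendritic cell and granulocyte markers 8 of 22 rose and 1 fell in MyD88 knockouts (3, 4 and 1 rose and 2, 4 and 1 fell by scaling, median 0.49, FDR = 0.61), whereas immediate early and heat shock genes in Tlr3 knockouts had 11 of 28 rise and 1 fall (6, 4 and 2 by scaling, median 0.51, FDR = 0.11, called after normexp, without the filter and without knockout or wild type replicate 4 at 0.018 to 0.038).

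The splits and the tests near the targeted genes were chosen before the data were examined. In each of the 8 comparisons only the real one of 35 splits of its 8 arrays called as many features, the lowest share possible. Real and highest other counts against wild type were 9628 and 3168 for Trif, 8413 and 4 for Tlr3 and 2762 and 0 for Tlr4. For Trif against Tlr3, Tlr4 and MyD88 they were 4398 and 759, 8893 and 4252 and 13887 and 4737. For MyD88 they were 10672 and 2530 against wild type and 10292 and 240 against Tlr4. For Tlr4 knockouts, paired with wild type by slide, 7 other splits part all 4 slides, too few to exclude chance, and called 0 features. A flanking segment that came with the mutated gene could make called features more frequent within 20 Mb of it. The odds ratio was 0.779 (Fisher's exact p = 0.026) around Ticam1 in Trif mutants, 1.34 (p = 0.06) around Tlr3, 0.838 (p = 0.51) around Tlr4 and 1.22 (p = 0.07) around Myd88. For changes of at least 4-fold it was 1.18, 3.34, 1.25 and 0.443. All leave it open.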
